A study of Arabidopsis thaliana with 30 samples.

How the data were processed

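The series holds 30 RNA sequencing libraries of the aerial parts of Arabidopsis thaliana Col-0 seedlings in 10 groups. Per the labels, seedlings grew for 6 days upright and 6 days flat under 16 h of light and 8 h of dark. They were then flooded with 1 of 2 Pseudomonas syringae strains at an optical density of 0.1, or with mock solution of 10 mM MgCl2 and 0.028% Silwet L-77. Per the labels' protocols, total RNA went into strand-specific libraries read as 150 bp pairs on a NovaSeq instrument, with 3 biological replicates per group, all in batch 1. When untreated seedlings were harvested and at what hour treatments began is not given.

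The deposit gives the authors' raw counts per gene. The submitters' processing notes name fastp 0.23.2, HISAT2 2.2.1, featureCounts 2.0.1, DESeq2 1.34.0 and R 4.1.0 and the build TAIR10. Settings of these tools, use of the strand and handling of reads that fit more than 1 gene are not given. Of counts from 1 to 20, 72.3% were even, so that the 2 mates of a pair appear to have been counted one by one, and a count is then not an independent fragment. The total was 47100493 to 54296791 counts per library, and genes of the organelles held 0.0299% to 0.348%. Of 32833 genes 5728 had no count. The reference annotation, TAIR10.1, served for gene names and gene overlaps only.

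Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10, which left 21584, and scaled by TMM, with factors of 0.841 to 1.18. The lowest factor was that of replicate 2 of AvrRpt2 at 6 h. A robust quasi-likelihood fit with 1 mean per group over all 30 libraries, with 20 residual degrees of freedom and a common dispersion of 0.0119, gave F-tests of 17 comparisons. They were each strain against mock and the strains against each other at 3 times, mock against untreated and between times, and 3 tests of whether an effect differs between 20 and 6 h. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes. CPM uses the scaled totals.

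Gene lists were fixed before the data were examined: 19 lists with 385 genes for salicylic acid and N-hydroxypipecolic acid, NLR receptors and helpers, pattern-triggered immunity, WRKY factors, camalexin and indole glucosinolates, jasmonate, ethylene, abscisic acid, auxin, photosynthesis, cell cycle, clock, endoplasmic reticulum chaperones, hypoxia, glutathione transferases and cell death, with markers of root, guard cell and vascular tissue. Each was tested with camera (preset correlation 0.01, adjusted over the 19 lists), with camera and an estimated correlation, and with fry, a test against no change. In 35 of 323 list tests the median, the mean and the test differed in sign, none of them passed. A rule fixed with the lists lets the text name up to 4 called members of a list with the largest change. Members whose call or direction changed under another setting or without 1 library were then not used as examples. This choice came after those results and is not in the rule. Of 1029 called members the rule allows 181 changed in this way, against 2 of 54 named, so the examples are steadier than the lists they come from. Also named are the 5 largest rises and falls (3 in mock and interaction comparisons) of called genes averaging at least 5 CPM. Outside interactions, the groups do not overlap. PR1, ICS1, FMO1, PAD3, FRK1, RPS2, RPS4, RRS1, RIN4, EDS1 and CCA1 appear everywhere.

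The tests were checked on simulated data for AvrRpt2 against mock at 6 h with 200 changed genes. At 2-fold the edgeR test found 79.5% of them, and 12.6% of its calls were false, above the adjusted p limit. These rates may not hold where far more genes change. Alternatives were DESeq2 1.42.0, RLE and total count scaling, no low-count filter, a fit of the compared groups alone, a 2-fold minimum, replicate number as a block and each library left out. Halved and rounded counts were added after the even counts were seen. Groups were also split anew in all 10 ways, or in 100 draws for the interactions. Raw reads were not used, and matplotlib 3.10.9 drew the figures.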

Results

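Gene expression was measured by RNA sequencing in aerial parts of Arabidopsis thaliana Col-0 seedlings flooded with bacteria or mock. The bacteria were Pseudomonas syringae pv. tomato DC3000, a leaf pathogen of tomato and Arabidopsis, in 2 versions. AvrRpt2 is an effector protein that Col-0 detects through the receptor RPS2, and AvrRps4 is detected through the receptor pair RRS1 and RPS4. The mock was MgCl2 with Silwet L-77, a surfactant that wets the leaf. Seedlings were taken at 6, 12 and 20 h, and an untreated group has no stated time. Each of the 10 groups held 3 replicates.

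Values are log2 fold changes ± a rough standard error (fit of all 30 libraries, 3 per group). Levels in CPM (counts scaled to one library size) are mean ± SD over 3 libraries. A fold against a group with no count is given as "at least" over a floor of 3 counts in that group. With 1 to 3 counts the 95% counting interval of the ratio is given. Intervals and floors cover counting error only. Outside interactions, genes of the largest change had all 3 libraries of a group beyond the other 3. Chance gives this in 10% of unchanged genes. Groups of genes are 19 lists, among them pattern-triggered immunity (PTI), indolic defence (camalexin and indole glucosinolates), glutathione transferases (GST) and the intracellular NLR receptors with their helpers, and the adjusted p of a list is from the camera test of its members against all other genes. Where a list passed with the preset correlation between genes but not with an estimated one, the adjusted p of the latter follows, in the order in which the lists are named. Numbers that rose and fell when adjusted over the list alone ("list alone") are given where they differ from those over all genes. Pairs such as 4 and 12 of 25 give the members that moved up and down. Calls that change when 1 library is left out are given with the adjusted p and the groups and replicate numbers of those libraries, then called values it moved over 1.5-fold (the fitted value follows "from" where the text gives levels or an interval) and calls ended by another setting. The fry test asks whether the members shifted in 1 direction, and lists that passed camera but not fry are named. Values of close copies, such as PDF1.2, SAUR19 to SAUR24, LHCB1, LHCB2 and RBCS genes, are uncertain, as handling of shared reads is not given.

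The first principal component held 43.5% of the variance and the second 30.2%. Inoculated seedlings at 20 h lay far from every mock group. The untreated group lay nearest to mock at 20 h, at a root mean square distance of 0.592 log2 units, and 1.54 from mock at 6 h. At each time the 2 strains lay closer to one another (0.337, 0.349 and 0.464 at 6, 12 and 20 h) than to the mock of that time.

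**Figure D1:**
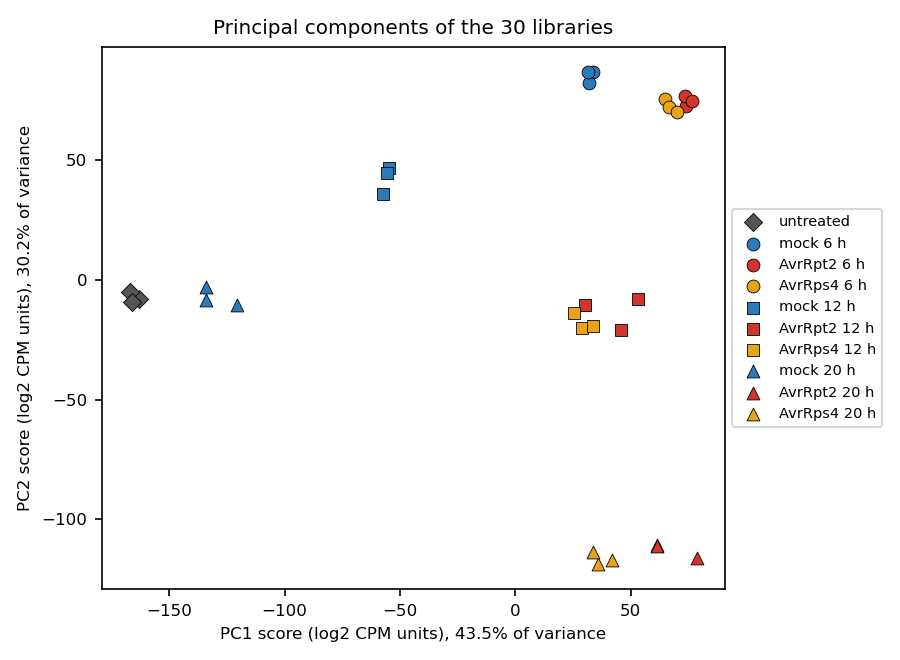
Principal components of log2 CPM of the tested genes, 1 point per library. Colours are treatments and symbols are harvest times.

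At 6 h the largest rises with the AvrRpt2 strain against mock included jasmonate genes. They were in JAZ8 (AT1G30135, a repressor of jasmonate signalling, 4.2 ± 0.21), CYP94C1 (AT2G27690, which oxidises jasmonoyl-isoleucine, 3.88 ± 0.30) and ST2A (AT5G07010, a sulfotransferase acting on hydroxyjasmonate, 3.29 ± 0.38), followed by HAK5 (AT4G13420, 3.17 ± 0.46) and the unnamed gene AT3G43250 (3.06 ± 0.25). The largest falls were in the SAUR-like auxin genes AT4G38860 (-2.22 ± 0.16), AT4G38840 (-1.60 ± 0.14) and AT1G56150 (-1.58 ± 0.17), and in CYP710A2 (AT2G34490, -1.56 ± 0.23) and WAK2 (AT1G21270, -1.52 ± 0.15). In all, 23 of 30 jasmonate genes rose and 0 fell (median 1.3, list alone 24 and 1, adjusted p = 7.58e-52), among them JAZ7 (AT2G34600, 2.48 ± 0.28). 17 of 22 indolic defence genes rose and 0 fell (median 1.05, adjusted p = 8.43e-23), with MYB122 (AT1G74080, an activator of indole glucosinolate synthesis, 2.43 ± 0.30). A further 14 of 24 PTI genes rose and 2 fell (median 0.40, list alone 16 and 2, adjusted p = 8.05e-10), with PROPEP3 (AT5G64905, 1.76 ± 0.33). 11 of 23 WRKY genes rose and 1 fell (median 0.60 or 0.57 with genes at 0 set to the floor, list alone 12 and 2, adjusted p = 1.14e-06), with WRKY75 (AT5G13080, 2.32 ± 0.14), and 10 of 19 ethylene genes rose and 2 fell (median 0.35, list alone 11 and 2, adjusted p = 1.39e-05), with ORA59 (AT1G06160, an activator of defensin genes, 1.85 ± 0.20). Numbers that rose and fell were 6 and 1 of 25 salicylic acid genes (list alone 8 and 2), 11 and 0 of 14 GST genes, 6 and 2 of 15 cell death genes (list alone 8 and 2), 0 and 17 of 38 photosynthesis genes (list alone 0 and 22) and 0 and 2 of 10 guard cell markers. Adjusted p was 1.08e-07 to 0.0337, and adjusted p = 0.437, 0.103, 0.140, 0.433 and 0.0920 with an estimated correlation. The remaining lists had adjusted p from 0.131 to 0.970. Of the single genes followed in every comparison PAD3 (AT3G26830, the last enzyme of camalexin synthesis, 1.2 ± 0.22), FRK1 (AT2G19190, a marker of pattern-triggered immunity, 1.2 ± 0.19) and EDS1 (AT3G48090, a hub of signalling from TIR-type receptors, -0.37 ± 0.13) changed. The others did not pass, with values of PR1 (AT2G14610, a marker of the salicylic acid response, 0.68 ± 1.05), ICS1 (AT1G74710, isochorismate synthase, 0.46 ± 0.27), FMO1 (AT1G19250, which makes N-hydroxypipecolic acid, 0.88 ± 1.14), RPS4 (AT5G45250, part of the AvrRps4 receptor pair, 0.19 ± 0.09), RRS1 (AT5G45260, the partner of RPS4, 0.09 ± 0.12), RIN4 (AT3G25070, the target of AvrRpt2 guarded by RPS2, 0.12 ± 0.07) and CCA1 (AT2G46830, a morning gene of the clock, -0.13 ± 0.13) (adjusted p from 0.123 to 0.702). In total 4977 of 21584 genes changed, 2636 upward. With scaling by total counts alone 1974 rose and 4271 fell. Without 1 library the call changed (adjusted p) for EDS1 (0.0522 to 0.189, mock 1 and 3 and AvrRpt2 1 and 2), RPS4 (0.0165, AvrRpt2 2) and the guard cell markers (0.0800, AvrRpt2 2). Other settings ended calls (adjusted p): EDS1 (0.0509) with RLE scaling.

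With the AvrRps4 strain at 6 h CYP94C1 (4.52 ± 0.31), JAZ8 (4.37 ± 0.21) and ST2A (4.03 ± 0.38) rose most, with AT3G43250 (3.12 ± 0.25) and HAK5 (3.06 ± 0.46). AT4G30650 (-1.46 ± 0.19), AT1G21520 (-1.46 ± 0.18) and WRKY30 (AT5G24110, -1.45 ± 0.19), and WAK2 (-1.45 ± 0.15) and AT4G11000 (-1.35 ± 0.34), fell most. Here 24 of 30 jasmonate genes rose and 1 fell (median 1.47, adjusted p = 1.83e-70), among them JAZ7 (2.94 ± 0.27). Beside these 16 of 22 indolic defence genes rose and 0 fell (median 1.0, list alone 17 and 1, adjusted p = 3.19e-31), with CYP79B2 (AT4G39950, the entry enzyme of indolic defence compounds, 2.51 ± 0.17). Of immune genes 14 of 24 PTI genes rose and 1 fell (median 0.29, list alone 14 and 3, adjusted p = 2.81e-10), with PEPR2 (AT1G17750, 1.86 ± 0.14). 9 of 19 ethylene genes rose and 0 fell (median 0.44, list alone 11 and 0, adjusted p = 4.20e-07), with ORA59 (1.95 ± 0.20). Weaker support was found for rises and falls in 7 and 0 of 25 salicylic acid genes (list alone 8 and 0), 10 and 1 of 23 WRKY genes, 8 and 0 of 14 GST genes, 5 and 1 of 15 cell death genes and 0 and 19 of 38 photosynthesis genes (list alone 0 and 25). Adjusted p was 7.87e-09 to 0.0178, and adjusted p = 0.425, 0.124, 0.317, 0.317 and 0.371 with an estimated correlation. The cell death median was 0.07, or -0.01 with scaling by total counts alone. The other lists did not pass (adjusted p from 0.0863 to 0.635). PAD3 (1.21 ± 0.22) and FRK1 (1.31 ± 0.19) were the only genes of the fixed set to pass. Values below the call were PR1 (0.79 ± 1.03), ICS1 (0.40 ± 0.27), FMO1 (0.93 ± 1.13), RPS4 (0.23 ± 0.09), RRS1 (0.13 ± 0.12), RIN4 (0.04 ± 0.07), EDS1 (-0.29 ± 0.13) and CCA1 (0.12 ± 0.13) (adjusted p from 0.0712 to 0.739). The test called 3831 genes, 1992 of them upward, and with scaling by total counts alone 1552 rose and 3345 fell.

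With AvrRpt2 at 12 h MSRB7 (AT4G21830, a methionine sulfoxide reductase, 8.05 ± 0.39), ST2A (6.88 ± 0.39) and MDHAR (AT3G09940, a monodehydroascorbate reductase, 6.87 ± 0.43) rose most, with PDF1.2b (AT2G26020, a plant defensin, 6.27 ± 0.41) and PDF1.2c (AT5G44430, 6.05 ± 0.62). GASA6 (AT1G74670, a gibberellin-regulated peptide, -5.30 ± 0.30), FBA5 (AT4G26530, -3.87 ± 0.18) and CYP707A2 (AT2G29090, an abscisic acid hydroxylase, -3.69 ± 0.31), and AT2G15020 (-4.24 ± 0.29) and AMT1;2 (AT1G64780, -3.56 ± 0.18), fell most. PBS3 (AT5G13320, which conjugates isochorismate to glutamate, 4.14 ± 0.53) and NIMIN1 (AT1G02450, 3.98 ± 1.09) rose among the salicylic acid genes. In mock at 12 h 22 of 25 salicylic acid genes were higher in replicate 1 than in both other replicates. 22 of 22 indolic defence genes rose and 0 fell (median 2.34, adjusted p = 1.28e-33), with CYP82C2 (AT4G31970, which makes 4-hydroxyindole-3-carbonyl nitrile, 145-fold to 32039-fold by the interval), and 29 of 30 jasmonate genes rose and 1 fell (median 3.19, adjusted p = 1.53e-47), with CYP94C1 (5.80 ± 0.35). 16 of 19 ethylene genes rose and 0 fell (median 1.0, adjusted p = 2.09e-09), with ERF1 (AT3G23240, an ethylene response factor, 2.99 ± 0.22). 21 of 24 PTI genes rose and 1 fell (median 1.17, adjusted p = 1.43e-17), with PROPEP2 (AT5G64890, the precursor of a danger peptide, 6.25 ± 0.46), and 16 of 23 WRKY genes rose and 1 fell (median 1.35 or 1.31 with genes at 0 set to the floor, adjusted p = 1.67e-08), with WRKY75 (3.33 ± 0.14). Upward and downward changes with weaker support were in 24 and 0 of 25 salicylic acid genes, 11 and 0 of 16 NLR genes, 15 and 1 of 16 chaperone genes, 11 and 2 of 15 cell death genes (list alone 12 and 2) and 10 and 2 of 14 GST genes. Adjusted p was 3.67e-08 to 0.00378, and adjusted p = 0.117, 0.243, 0.103, 0.0869 and 0.243 with an estimated correlation. The falling lists had 0 and 38 of 38 photosynthesis genes and 4 and 12 of 25 auxin genes (list alone 5 and 13). Adjusted p was 7.86e-15 to 0.0397, and adjusted p = 0.177 and 0.165 with an estimated correlation. No other list passed (adjusted p from 0.117 to 0.911). Every measured gene of the fixed set changed, namely PR1 (4.4 ± 0.75), ICS1 (2.35 ± 0.27), FMO1 (3.77 ± 0.69), PAD3 (2.14 ± 0.22), FRK1 (3.26 ± 0.22), RPS4 (0.64 ± 0.09), RRS1 (0.43 ± 0.12), RIN4 (0.87 ± 0.07), EDS1 (0.81 ± 0.13) and CCA1 (-0.83 ± 0.15). Altogether 11820 genes changed, 5199 up and 6621 down. RLE scaling gave 5743 and 5832 and total count scaling 4638 and 7412. Leaving out 1 library changed the call (adjusted p) of the auxin genes (0.0607 to 0.0685, AvrRpt2 2 and 3). Moved by over 1.5-fold, values were 8.72 for MSRB7, 7.48 for ST2A, 8.31 for MDHAR, 6.04 for PBS3, 7.31 for NIMIN1, 6.48 for CYP94C1, 3.02 for ICS1 and 6.98 for FMO1 without mock 1, -6.26 for GASA6 without AvrRpt2 1 and 10.85 for CYP82C2 (from 9.14) without mock 2. Calls that ended with other settings (adjusted p) were those of FMO1 (0.0857) with only these groups fitted, the auxin genes (0.0596) with total count scaling and the auxin genes (0.0598) with halved counts.

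The AvrRps4 strain at 12 h had its largest rises in MSRB7 (9.01 ± 0.40), MDHAR (8.26 ± 0.44) and ST2A (7.51 ± 0.40), with DIR5 (AT1G64160, 7.46 ± 0.37) and PDF1.2b (7.34 ± 0.42). The largest falls were again in GASA6 (-6.29 ± 0.34), FBA5 (-3.71 ± 0.18) and CYP707A2 (-3.62 ± 0.31), with AMT1;2 (-3.77 ± 0.18) and AT2G15020 (-3.70 ± 0.28). UGT76B1 (AT3G11340, 3.16 ± 0.24) rose among the salicylic acid genes. 29 of 30 jasmonate genes rose and 0 fell (median 3.47, adjusted p = 4.82e-59), with CYP94C1 (6.39 ± 0.35), and 15 of 19 ethylene genes rose and 0 fell (median 0.90, adjusted p = 2.58e-08), with ERF1 (2.95 ± 0.22). 22 of 22 indolic defence genes rose and 0 fell (median 2.28, adjusted p = 2.31e-31), with CYP82C2 (34.9-fold to 7820.5-fold by the interval). 20 of 24 PTI genes rose and 1 fell (median 0.91, adjusted p = 1.33e-12), with PROPEP2 (5.38 ± 0.49). Rising lists with weaker support had 19 and 0 of 25 salicylic acid genes, 15 and 1 of 23 WRKY genes, 13 and 1 of 16 chaperone genes, 12 and 2 of 15 cell death genes and 10 and 2 of 14 GST genes. Adjusted p was 2.58e-08 to 0.00926, and adjusted p = 0.252, 0.0588, 0.0724, 0.120 and 0.402 with an estimated correlation. Mostly falling were 0 and 36 of 38 photosynthesis genes (list alone 0 and 37) and 4 and 11 of 25 auxin genes. Adjusted p was 1.65e-07 to 0.0303, and adjusted p = 0.402 and 0.136 with an estimated correlation. Other lists stayed below the call (adjusted p from 0.0532 to 0.968). From the fixed set PR1 (2.63 ± 0.74), ICS1 (1.18 ± 0.27), FMO1 (2.12 ± 0.66), PAD3 (1.67 ± 0.22), FRK1 (3.32 ± 0.22), RPS4 (0.22 ± 0.09), RIN4 (0.72 ± 0.07), EDS1 (0.47 ± 0.13) and CCA1 (-0.60 ± 0.15) changed. RRS1 (0.16 ± 0.12, adjusted p = 0.294) did not. In all 11271 genes passed, 4971 up and 6300 down. Calls that turned without 1 library (adjusted p) were those of RPS4 (0.0523 to 0.158, mock 1, 2 and 3 and AvrRps4 1 and 3), RRS1 (0.0417, AvrRps4 2) and the auxin genes (0.0565, AvrRps4 3). Over 1.5-fold moves were to 9.67 for MSRB7, 9.69 for MDHAR, 8.11 for ST2A, 7.06 for CYP94C1, 1.85 for ICS1 and 5.32 for FMO1 without mock 1 and 8.81 for CYP82C2 (from 7.10) without mock 2. The call ended (adjusted p) for FMO1 (0.277) and ICS1 (0.0936) with only these groups fitted and RPS4 (0.159) with total count scaling.

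At 20 h about 3 in 4 tested genes (76.2%) differed between AvrRpt2 and mock. Among genes without a count in mock, PCK2 (AT5G65690, at least 812-fold) and PROPEP2 (at least 524-fold), the peroxidase gene AT1G14550 (at least 789-fold), and CYP71B21 (AT3G26190, at least 430.0-fold) and AT5G37840 (at least 404-fold) rose most. The largest falls were in FBA5 (-7.27 ± 0.23), GASA6 (-6.94 ± 0.31) and NAS4 (AT1G56430, -5.99 ± 0.38) and in AT2G27420 (-7.99 ± 0.41) and AT1G29430 (-7.10 ± 0.72). 30 of 30 jasmonate genes rose and 0 fell (median 3.92, adjusted p = 8.23e-21), with BSMT1 (AT3G11480, a methyltransferase of salicylic acid, 8.01 ± 0.52). 22 of 22 indolic defence genes rose and 0 fell (median 3.55, adjusted p = 2.06e-18), with MYB122 (7.5 ± 0.39). 21 of 24 PTI genes rose and 2 fell (median 2.04, adjusted p = 1.09e-12), with PROPEP3 (8.42 ± 0.53), and 22 of 23 WRKY genes rose and 1 fell (median 2.91, adjusted p = 4.85e-08), with WRKY51 (AT5G64810, 6.64 ± 0.67). 17 of 19 ethylene genes rose and 0 fell (median 1.72, adjusted p = 7.52e-07), with ERF1 (5.33 ± 0.26), and 12 of 15 cell death genes rose and 2 fell (median 1.89, adjusted p = 1.50e-06), with BAP2 (AT2G45760, a suppressor of cell death, 9.86 ± 0.52). Mostly rising were 24 and 0 of 25 salicylic acid genes, 15 and 0 of 16 NLR genes, 14 and 5 of 23 abscisic acid genes, 15 and 0 of 16 chaperone genes and 11 and 2 of 14 GST genes. Adjusted p was 4.85e-08 to 0.0382, and adjusted p = 0.112, 0.0841, 0.153, 0.143 and 0.153 with an estimated correlation. Mostly falling were 6 and 19 of 25 auxin genes, 0 and 38 of 38 photosynthesis genes and 0 and 19 of 21 cell cycle genes. Adjusted p was 8.23e-21 to 0.0141, and adjusted p = 0.0654, 0.0870 and 0.526 with an estimated correlation. Other lists had adjusted p from 0.0664 to 0.911. PR1 (5.63 ± 0.79), ICS1 (3.82 ± 0.28), FMO1 (8.82 ± 0.95), PAD3 (3.89 ± 0.24), FRK1 (5.38 ± 0.25), RPS4 (1.55 ± 0.09), RRS1 (0.56 ± 0.12), RIN4 (1.33 ± 0.07), EDS1 (1.69 ± 0.13) and CCA1 (-0.50 ± 0.12) all changed. Of the 16453 genes called 8116 rose and 8337 fell. Scaling by total counts alone moves the median of all genes by -0.12. Values that moved over 1.5-fold became -6.69 for NAS4 without AvrRpt2 2, 8.80 for BSMT1, 8.58 for MYB122, 11.88 for PROPEP3 and 6.6 for PR1 without mock 2 and 10.81 for BAP2 without mock 3.

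The AvrRps4 strain at 20 h changed 15580 genes, 7763 upward and 7817 downward. The lectin-like genes AT1G52120 (at least 664-fold) and AT1G52110 (at least 333-fold), then PCK2 (at least 454-fold) and TPS02 (AT4G16730, at least 358-fold) and GH9B15 (AT4G23560, 773-fold to 23086-fold by the interval), rose most. Largest among the falls were GASA6 (-7.89 ± 0.33) and FBA5 (-6.53 ± 0.22), AT2G27420 (-6.91 ± 0.37) and AT3G06145 (-6.30 ± 0.30) and M17 (AT2G41260, -5.79 ± 0.38). 30 of 30 jasmonate genes rose and 0 fell (median 3.91, adjusted p = 1.50e-28), with BSMT1 (8.64 ± 0.52). 22 of 22 indolic defence genes rose and 0 fell (median 2.63, adjusted p = 2.58e-16), with MYB122 (6.6 ± 0.39). 21 of 24 PTI genes rose and 3 fell (median 1.68, adjusted p = 4.73e-10), with PROPEP2 (at least 189-fold), and 22 of 23 WRKY genes rose and 1 fell (median 2.43, adjusted p = 5.18e-09), with WRKY51 (6.57 ± 0.67). 17 of 19 ethylene genes rose and 1 fell (median 1.03, adjusted p = 6.57e-05), with ACS2 (AT1G01480, of ethylene synthesis, 4.81 ± 0.25), and 12 of 15 cell death genes rose and 2 fell (median 1.17, adjusted p = 7.81e-06), with BAP2 (9.05 ± 0.52). Upward lists with weaker support had 25 and 0 of 25 salicylic acid genes, 13 and 0 of 16 NLR genes, 15 and 4 of 23 abscisic acid genes, 16 and 0 of 16 chaperone genes and 10 and 2 of 14 GST genes. Adjusted p was 4.73e-10 to 0.00352, and adjusted p = 0.0714, 0.0724, 0.0656, 0.164 and 0.270 with an estimated correlation. Downward lists had 0 and 38 of 38 photosynthesis genes, 6 and 18 of 25 auxin genes and 0 and 17 of 21 cell cycle genes. Adjusted p was 5.46e-18 to 0.0240, and adjusted p = 0.107, 0.0549 and 0.588 with an estimated correlation. Lists without a call had adjusted p from 0.232 to 0.699. PR1 (4.24 ± 0.77), ICS1 (4.43 ± 0.29), FMO1 (8.67 ± 0.95), PAD3 (2.47 ± 0.23), FRK1 (4.92 ± 0.25), RPS4 (1.17 ± 0.09), RIN4 (1.26 ± 0.07) and EDS1 (1.99 ± 0.13) changed, and RRS1 (0.24 ± 0.12) and CCA1 (-0.17 ± 0.12) (adjusted p from 0.0863 to 0.214) did not. Without 1 library the call changed (adjusted p) for RRS1 (0.0463 to 0.0469, mock 2 and AvrRps4 3). Moved by over 1.5-fold, values were 13.77 for GH9B15 (from 11.18) and 10.00 for BAP2 without mock 3, -8.63 for GASA6 and -7.61 for AT2G27420 without AvrRps4 2 and 9.43 for BSMT1, 7.68 for MYB122 and 5.22 for PR1 without mock 2.

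**Figure D2:**
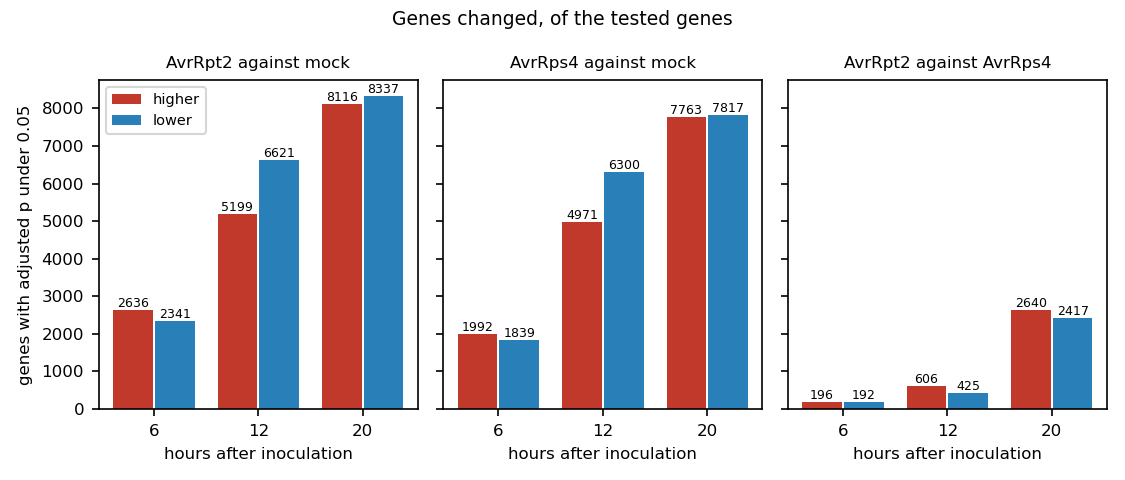
Numbers of genes higher and lower with each strain against mock, and with AvrRpt2 against AvrRps4, at 6, 12 and 20 h. Bars count genes with adjusted p under 0.05.

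The responses to the 2 strains, each of which includes the response to the bacteria as such, overlapped. At 6 h 1599 genes were higher and 1102 lower with both strains, at 12 h 4268 and 5311, and at 20 h 7246 and 7282. Independent lists of these sizes would share 243 and 199, 1197 and 1933, and 2919 and 3019. Genes called in opposite directions numbered 2, 11 and 40. The log2 fold changes correlated with r = 0.650, 0.891 and 0.944. Simulated groups without any change that share 3 mock libraries gave a mean r of 0.508, 0.499 and 0.490. The covariance was 0.272, 0.907 and 2.65, against simulated means of 0.0714, 0.0629 and 0.0645. Genes are not independent of one another, and the 3 mock libraries of a time cannot be split, so part of the excess may come from the shared controls. The median absolute log2 fold change grew from 0.215 to 0.860 with AvrRpt2 and from 0.192 to 0.716 with AvrRps4 between 6 and 20 h.

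**Figure D3:**
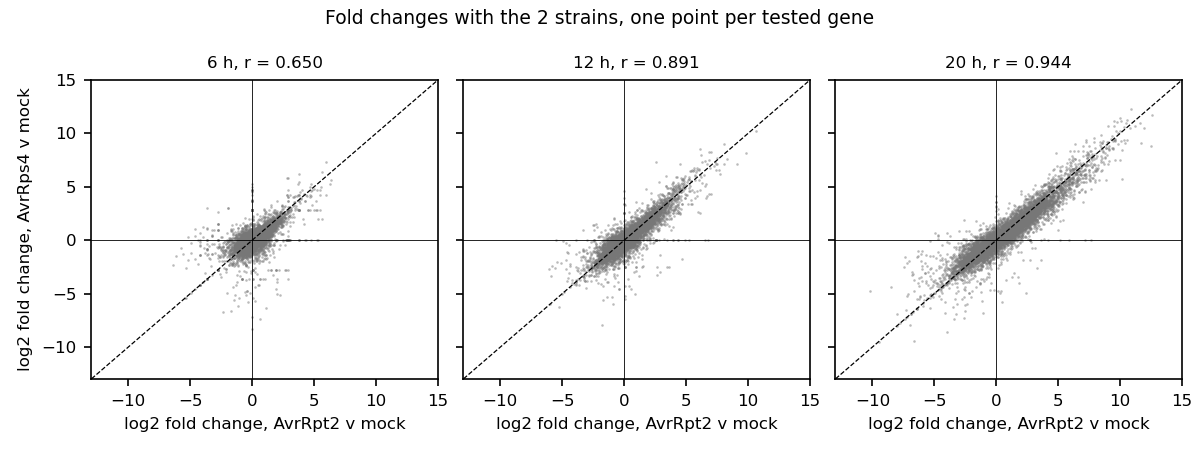
Log2 fold changes against mock with AvrRpt2 (horizontal) and AvrRps4 (vertical) at 6, 12 and 20 h, 1 point per tested gene. Both axes share the 3 mock libraries of the time.

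Few genes differed between the strains at 6 h. ZAT7 (AT3G46090, a zinc-finger protein, 1.25 ± 0.23), AT3G46080 (1.18 ± 0.24) and OXS3 (AT5G56550, 1.16 ± 0.22), and AT5G54165 (1.15 ± 0.28) and AT1G14200 (1.15 ± 0.18), were higher with AvrRpt2. NRT1.8 (AT4G21680, a nitrate transporter, -1.15 ± 0.22), CRF3 (AT5G53290, -1.03 ± 0.24) and GPRI1 (AT2G20570, -0.83 ± 0.10), and AT4G38840 (-0.99 ± 0.15) and AT3G25700 (-0.82 ± 0.16), were lower. Higher and lower were 1 and 0 of 14 hypoxia genes (list alone 5 and 0) and 2 and 0 of 14 GST genes. Adjusted p was 0.00452 to 0.00649, and adjusted p = 0.987 and 0.987 with an estimated correlation. The hypoxia gene was HRA1 (AT3G10040, a regulator of the hypoxia response, 1.82 ± 0.44), and GSTU7 (AT2G29420, 0.52 ± 0.13) was among the GST genes. None of the other lists passed (adjusted p from 0.130 to 0.956). None of the fixed set passed: PR1 (-0.11 ± 0.97), ICS1 (0.06 ± 0.26), FMO1 (-0.06 ± 1.03), PAD3 (-0.01 ± 0.21), FRK1 (-0.10 ± 0.19), RPS4 (-0.04 ± 0.09), RRS1 (-0.03 ± 0.12), RIN4 (0.08 ± 0.07), EDS1 (-0.09 ± 0.13) and CCA1 (-0.25 ± 0.13) (adjusted p from 0.340 to 0.994). Of 388 genes called 196 were higher with AvrRpt2. With only these 2 groups in the fit 220 were called, 69.1% of them higher, and without 1 library the number ran from 38 (AvrRps4 replicate 1) to 527 (AvrRps4 replicate 3), with 68 without AvrRps4 replicate 2, 160 without AvrRpt2 replicate 1 and 130 without AvrRpt2 replicate 2. Leaving out 1 library changed the call (adjusted p) of ZAT7 (0.0681, AvrRps4 1), AT3G46080 (0.0790 to 0.121, AvrRpt2 2 and AvrRps4 1 and 2), OXS3 (0.0679 to 0.0731, AvrRps4 1 and 2), AT5G54165 (0.0621 to 0.222, AvrRpt2 1 and 2 and AvrRps4 1 and 2), NRT1.8 (0.0588 to 0.0655, AvrRpt2 2 and AvrRps4 1 and 2), CRF3 (0.0582 to 0.149, AvrRpt2 2 and 3 and AvrRps4 1 and 2), AT3G25700 (0.0741, AvrRps4 1), HRA1 (0.0859 to 0.187, AvrRpt2 1 and 2 and AvrRps4 1 and 2) and GSTU7 (0.0639 to 0.186, AvrRpt2 1 and 2 and AvrRps4 1 and 2). Other settings ended calls (adjusted p): AT1G14200 (0.134), AT3G46080 (0.0670) and AT5G54165 (0.0984) with only these groups fitted, AT5G54165 (0.0517) and HRA1 (0.0545) with no low-count filter and HRA1 (0.0546) with halved counts. Fry did not call the GST genes (0.389) and the hypoxia genes (0.249).

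Between the strains at 12 h AT1G33055 (2.24 ± 0.50), HRA1 (2.17 ± 0.39) and BAP2 (1.64 ± 0.30), and AT2G15880 (2.14 ± 0.24) and WAK3 (AT1G21240, 1.63 ± 0.31), were highest against AvrRps4. Lower with AvrRpt2 were BSMT1 (-1.61 ± 0.41), OFP1 (AT5G01840, -1.48 ± 0.15) and MYB113 (AT1G66370, -1.28 ± 0.24), and MDHAR (-1.39 ± 0.29) and AT4G36430 (-1.25 ± 0.36). Hypoxia genes higher beside HRA1 were LBD41 (AT3G02550, a transcription factor induced by low oxygen, 1.44 ± 0.27), PCO1 (AT5G15120, a plant cysteine oxidase, 1.17 ± 0.26) and PCO2 (AT5G39890, a plant cysteine oxidase, 1.00 ± 0.22). Salicylic acid genes higher with AvrRpt2 included PAD4 (AT3G52430, a partner of EDS1, 1.02 ± 0.19). Members higher and lower were 5 and 0 of 14 hypoxia genes (list alone 7 and 0), 6 and 1 of 25 salicylic acid genes (list alone 15 and 1), 7 and 0 of 24 PTI genes (list alone 12 and 1), 3 and 0 of 16 NLR genes (list alone 7 and 0), 5 and 0 of 23 WRKY genes (list alone 6 and 1), 8 and 1 of 22 indolic defence genes (list alone 11 and 2) and 2 and 0 of 14 GST genes (list alone 2 and 1). Adjusted p was 8.54e-08 to 0.01, and adjusted p = 0.0946, 0.239, 0.0946, 0.132, 0.239, 0.274 and 0.400 with an estimated correlation. In the other direction were 1 and 5 of 30 jasmonate genes (list alone 1 and 8) and 0 and 9 of 38 photosynthesis genes (list alone 0 and 33). Adjusted p was 3.58e-17 to 4.22e-06, and adjusted p = 0.239 and 0.239 with an estimated correlation. The remaining lists did not pass (adjusted p from 0.0937 to 0.960). ICS1 (1.17 ± 0.26) and RPS4 (0.42 ± 0.09) differed, and PR1 (1.77 ± 0.63), FMO1 (1.66 ± 0.61), PAD3 (0.47 ± 0.21), FRK1 (-0.05 ± 0.19), RRS1 (0.27 ± 0.12), RIN4 (0.15 ± 0.07), EDS1 (0.34 ± 0.13) and CCA1 (-0.23 ± 0.16) (adjusted p from 0.111 to 0.918) did not. Of 1031 genes called, 606 were higher with AvrRpt2. The number was 563 with only these 2 groups in the fit, and 253, 1376 and 468 without AvrRpt2 replicates 1, 2 and 3, and 579 without AvrRps4 replicate 2. Calls that turned without 1 library (adjusted p) were those of AT1G33055 (0.0509 to 0.0562, AvrRpt2 1 and AvrRps4 1), BSMT1 (0.0716 to 0.175, AvrRpt2 1 and 2 and AvrRps4 1), MDHAR (0.0774, AvrRpt2 1), AT4G36430 (0.0556 to 0.211, AvrRpt2 1, 2 and 3 and AvrRps4 1 and 2), ICS1 (0.0701, AvrRpt2 3), PR1 (0.0279, AvrRpt2 2) and the GST genes (0.0530 to 0.188, AvrRpt2 1 and AvrRps4 1 and 3). Calls that ended with other settings (adjusted p) were those of HRA1 (0.0628) with only these groups fitted, AT4G36430 (0.0638) with no low-count filter and BSMT1 (0.132) with DESeq2. Fry did not call the indolic defence genes (0.0658) and the GST genes (0.145).

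At 20 h 5057 genes differed between the strains. AT1G14550 (3.70 ± 0.33), ARD3 (AT2G26400, of the methionine salvage cycle, 3.45 ± 0.71) and CYP82C2 (3.43 ± 0.38), and AT1G33055 (2.95 ± 0.54) and LBD41 (2.86 ± 0.29), were furthest above their level with AvrRps4, and scpl30 (AT4G15100, -2.06 ± 0.40), OFP1 (-1.73 ± 0.14) and AT2G44940 (-2.24 ± 0.21), and AT1G29100 (-2.00 ± 0.38) and AT1G75580 (-1.85 ± 0.21), furthest below. 18 of 22 indolic defence genes were higher and 2 lower (median 0.81, list alone 19 and 2, adjusted p = 3.67e-16), with FOX1 (AT1G26380, 2.1 ± 0.18) called. 13 of 24 PTI genes were higher and 0 lower (median 0.49, list alone 19 and 1, adjusted p = 3.12e-14), with NHL10 (AT2G35980, a marker of pattern-triggered immunity, 2.25 ± 0.29) called. 10 of 19 ethylene genes were higher and 0 lower (median 0.58, list alone 14 and 0, adjusted p = 1.10e-09), with ERF1 (1.08 ± 0.19) called. Less firm, with more members higher, were 6 and 0 of 14 hypoxia genes, 8 and 0 of 14 GST genes (list alone 9 and 0), 8 and 1 of 15 cell death genes (list alone 9 and 2), 9 and 0 of 16 chaperone genes (list alone 10 and 0), 6 and 1 of 16 NLR genes (list alone 7 and 1) and 8 and 4 of 23 WRKY genes. Adjusted p was 7.80e-07 to 0.0411, and adjusted p = 0.159, 0.159, 0.159, 0.246, 0.315 and 0.315 with an estimated correlation. With more members lower were 0 and 32 of 38 photosynthesis genes (list alone 0 and 38), 3 and 5 of 23 abscisic acid genes (list alone 3 and 7), 0 and 4 of 21 clock genes (list alone 0 and 3) and 0 and 3 of 12 vascular markers. Adjusted p was 3.12e-14 to 0.0411, and adjusted p = 0.243, 0.243, 0.246 and 0.256 with an estimated correlation. Lists without a call had adjusted p from 0.0638 to 0.747. PAD3 (1.42 ± 0.22), RPS4 (0.38 ± 0.09) and CCA1 (-0.33 ± 0.12) differed, and PR1 (1.38 ± 0.60), ICS1 (-0.61 ± 0.25), FMO1 (0.16 ± 0.59), FRK1 (0.46 ± 0.19), RRS1 (0.32 ± 0.12), RIN4 (0.07 ± 0.07) and EDS1 (-0.30 ± 0.12) (adjusted p from 0.0603 to 0.884) did not. Higher with AvrRpt2 were 2640 genes and lower 2417, or 2110 and 3272 with scaling by total counts alone. Without AvrRpt2 replicate 3 the number called was 3257. Without 1 library the call changed (adjusted p) for CCA1 (0.0726 to 0.160, AvrRpt2 1 and 2 and AvrRps4 1, 2 and 3), the NLR genes (0.0882, AvrRpt2 3), the WRKY genes (0.0640 to 0.0882, AvrRpt2 3 and AvrRps4 1), the abscisic acid genes (0.0743 to 0.0887, AvrRpt2 1 and 2 and AvrRps4 1 and 2), the clock genes (0.109, AvrRpt2 2) and the vascular markers (0.0588 to 0.0904, AvrRpt2 3 and AvrRps4 2 and 3). Over 1.5-fold moves were to 4.49 for ARD3 without AvrRps4 3. The call ended (adjusted p) for the abscisic acid genes (0.0619) and the NLR genes (0.0619) with total count scaling, CCA1 (0.0568) with RLE scaling and CCA1 (0.0544) with no low-count filter.

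**Figure D4:**
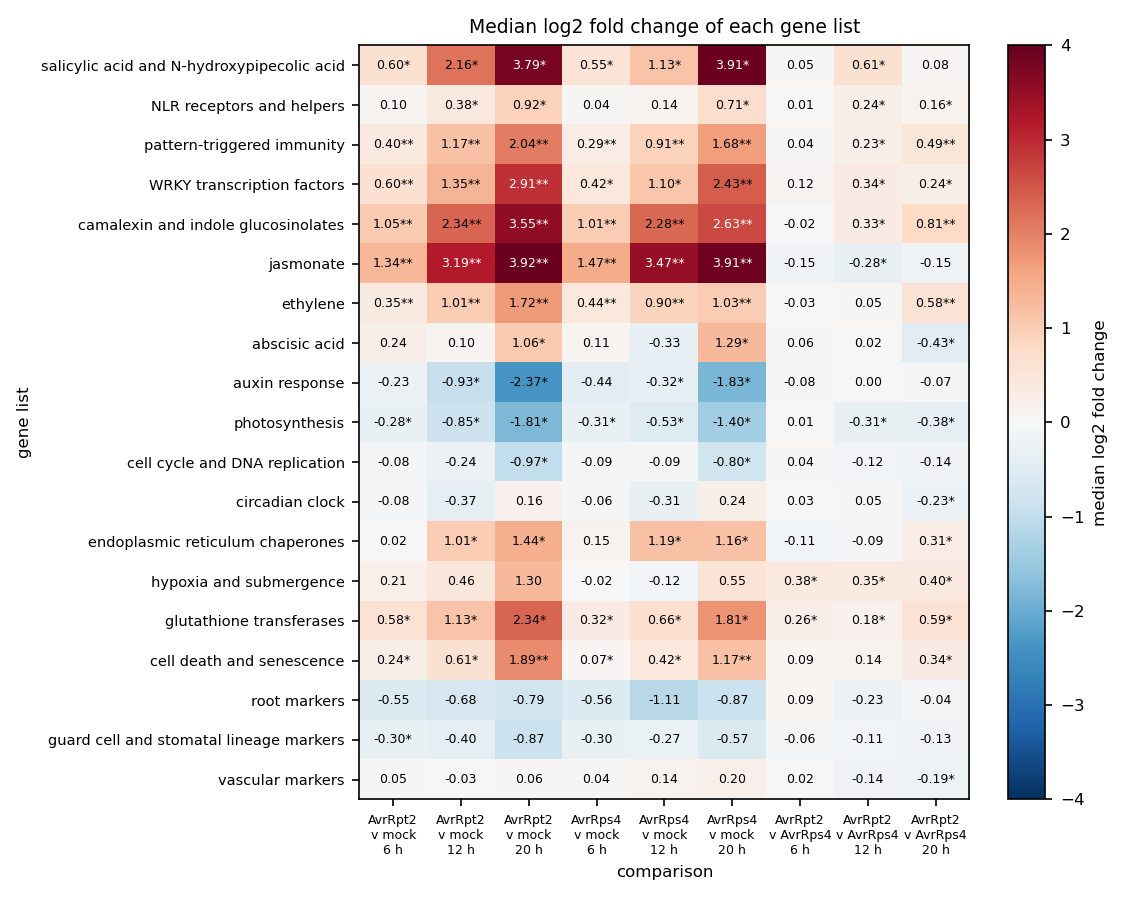
Median log2 fold change of each gene list with each strain against mock and between the strains. 1 star marks a list that passed the camera test, 2 stars one that passed with an estimated correlation too, and the cell death median with AvrRps4 at 6 h changes sign with scaling by total counts alone.

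**Figure D5:**
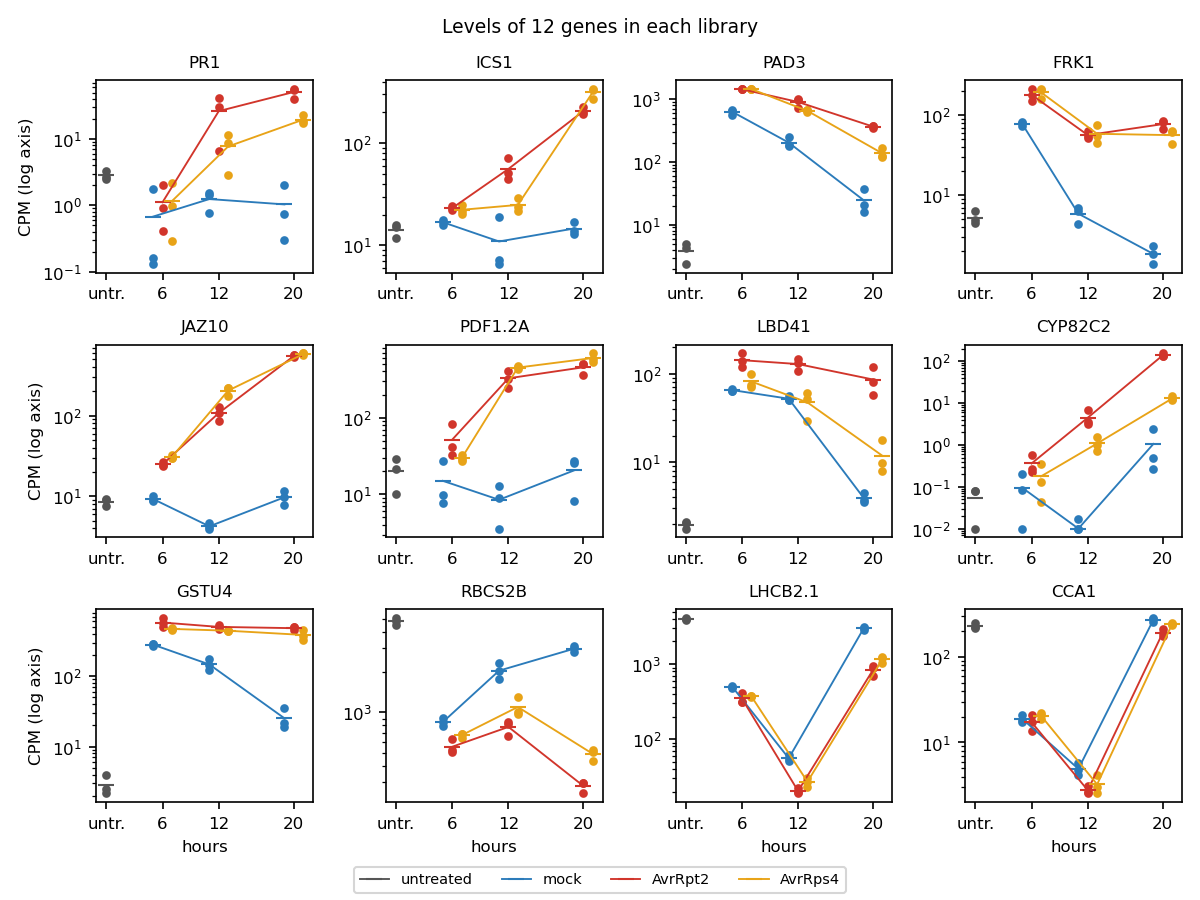
Levels of 12 genes in CPM on a logarithmic axis against hours after treatment. Points are libraries, lines join group means, and values under 0.01 are drawn at 0.01.

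The effect of the AvrRpt2 strain at 20 h was then tested against its effect at 6 h, each against the mock of its time. Here "rose" and "fell" mean a higher or lower effect at 20 h. The largest gains were in AT3G09950 (levels 0.0429, 0, 0.0124 and 15.8 CPM), GH9B15 (levels 0.0349, 0.0168, 0.0124 and 10.6 CPM) and AT5G37840 (levels 0.0134, 0.0319, 0 and 7.36 CPM), given as levels in mock and AvrRpt2 at 6 h, then at 20 h. FBA5 (-6.42 ± 0.29), GASA6 (-6.37 ± 0.41) and AT2G27420 (levels 0.0812, 0.0888, 32.1 and 0.125 CPM) lost most. 22 of 22 indolic defence genes rose and 0 fell (median 2.56, adjusted p = 3.18e-16), 20 of 24 PTI genes rose and 1 fell (median 1.5, adjusted p = 5.42e-12), and 19 of 23 WRKY genes rose and 1 fell (median 2.11, adjusted p = 3.43e-07). 29 of 30 jasmonate genes rose and 0 fell (median 2.34, adjusted p = 2.41e-12), and 16 of 19 ethylene genes rose and 1 fell (median 1.36, adjusted p = 1.78e-06). 12 of 15 cell death genes rose and 0 fell (median 1.54, adjusted p = 9.87e-07). Gains and losses with weaker support were 22 and 0 of 25 salicylic acid genes (list alone 23 and 0), 15 and 0 of 16 NLR genes, 12 and 4 of 23 abscisic acid genes, 9 and 2 of 14 GST genes and 15 and 0 of 16 chaperone genes. Adjusted p was 3.40e-09 to 0.0357, and adjusted p = 0.0805, 0.0595, 0.142, 0.266 and 0.0805 with an estimated correlation. Mostly losing were 0 and 38 of 38 photosynthesis genes, 5 and 11 of 25 auxin genes and 0 and 15 of 21 cell cycle genes (list alone 0 and 16). Adjusted p was 4.05e-21 to 0.0169, and adjusted p = 0.0805, 0.0805 and 0.482 with an estimated correlation. The difference between the effects passed for PR1 (4.95 ± 1.38), ICS1 (3.36 ± 0.38), FMO1 (7.95 ± 1.72), PAD3 (2.69 ± 0.31), FRK1 (4.18 ± 0.31), RPS4 (1.36 ± 0.13), RRS1 (0.46 ± 0.17), RIN4 (1.21 ± 0.10) and EDS1 (2.06 ± 0.18), and CCA1 (-0.37 ± 0.18, adjusted p = 0.0680) did not pass. In this test 13425 genes changed, 6895 upward. Leaving out 1 library changed the call (adjusted p) of AT5G37840 (1.00, mock 6 h 3), PR1 (0.325, mock 6 h 2), RRS1 (0.0728 to 0.0913, mock 6 h 1, AvrRpt2 6 h 2 and mock 20 h 3) and CCA1 (0.00974 to 0.0438, mock 6 h 2, AvrRpt2 6 h 2 and AvrRpt2 20 h 3). Values that moved over 1.5-fold became 13.36 for AT3G09950 (from 14.28) and 2.77 for PR1 without mock 6 h 2, 14.88 for AT3G09950 (from 14.28), 7.81 for AT5G37840 (from 10.57) and -9.95 for AT2G27420 (from -8.10) without mock 6 h 3, 16.87 for AT3G09950 (from 14.28) and 13.18 for GH9B15 (from 10.59) without mock 20 h 3, 13.47 for GH9B15 (from 10.59) and 5.67 for PR1 without AvrRpt2 6 h 2, 9.96 for AT5G37840 (from 10.57) without AvrRpt2 6 h 1 and 5.92 for PR1 without mock 20 h 2.

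For AvrRps4 the same test gave the largest gains in AT3G09950 (levels 0.0429, 0.0144, 0.0124 and 33.7 CPM), GH9B15 (levels 0.0349, 0.0149, 0.0124 and 33.9 CPM) and AT1G52120 (levels 0.119, 0.213, 0 and 12.1 CPM), as levels in the order mock and AvrRps4 at 6 h, then at 20 h. Losses were largest in GASA6 (levels 2.72, 1.1, 28.8 and 0.118 CPM), AT2G27420 (levels 0.0812, 0.0589, 32.1 and 0.263 CPM) and M17 (levels 1.65, 1.91, 7.47 and 0.133 CPM). 28 of 30 jasmonate genes rose and 0 fell (median 2.00, adjusted p = 2.31e-15). 19 of 24 PTI genes rose and 3 fell (median 1.02, adjusted p = 7.52e-08), 20 of 23 WRKY genes rose and 0 fell (median 1.96, adjusted p = 7.00e-08), and 19 of 22 indolic defence genes rose and 0 fell (median 1.66, adjusted p = 1.39e-09). 12 of 15 cell death genes rose and 1 fell (median 1.12, adjusted p = 4.50e-06). Gaining with weaker support were 23 and 0 of 25 salicylic acid genes, 12 and 0 of 16 NLR genes (list alone 13 and 0), 13 and 2 of 19 ethylene genes, 13 and 4 of 23 abscisic acid genes, 16 and 0 of 16 chaperone genes and 9 and 2 of 14 GST genes. Adjusted p was 3.29e-11 to 0.0110, and adjusted p = 0.0563, 0.0563, 0.0928, 0.0556, 0.151 and 0.370 with an estimated correlation. On the losing side were 0 and 37 of 38 photosynthesis genes (list alone 0 and 38), 5 and 13 of 25 auxin genes (list alone 5 and 14) and 0 and 9 of 21 cell cycle genes. Adjusted p was 2.31e-15 to 0.0183, and adjusted p = 0.140, 0.0973 and 0.521 with an estimated correlation. The difference passed for PR1 (3.46 ± 1.3), ICS1 (4.03 ± 0.38), FMO1 (7.73 ± 1.71), PAD3 (1.26 ± 0.31), FRK1 (3.62 ± 0.30), RPS4 (0.95 ± 0.13), RIN4 (1.22 ± 0.10) and EDS1 (2.27 ± 0.18) but not for RRS1 (0.11 ± 0.17) and CCA1 (-0.29 ± 0.18) (adjusted p from 0.167 to 0.606). Called genes numbered 12321, 6431 of them upward. Calls that turned without 1 library (adjusted p) were those of PR1 (0.0552 to 0.647, mock 6 h 2, AvrRps4 6 h 1 and 3 and mock 20 h 1 and 3). Moved by over 1.5-fold, values were 11.62 for AT3G09950 (from 12.55) and 1.27 for PR1 without mock 6 h 2, 13.14 for AT3G09950 (from 12.55) and -8.26 for AT2G27420 (from -6.41) without mock 6 h 3, 15.38 for AT3G09950 (from 12.55) and 4.33 for PR1 without AvrRps4 6 h 2, 15.14 for AT3G09950 (from 12.55) and 14.90 for GH9B15 (from 12.31) without mock 20 h 3, 15.14 for GH9B15 (from 12.31) without AvrRps4 6 h 3, -7.33 for GASA6 (from -6.59) and -7.12 for AT2G27420 (from -6.41) without AvrRps4 20 h 2 and 4.43 for PR1 without mock 20 h 2. Other settings ended calls (adjusted p): PR1 (0.0620) with only these groups fitted and PR1 (0.0626) with halved counts.

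The difference between the strains at 20 h was tested against that at 6 h. Levels are for AvrRps4 and AvrRpt2 at 6 h, then at 20 h. CYP82C3 (AT4G31950, levels 0.476, 0.0737, 1.37 and 6.84 CPM), ARD3 (levels 0.132, 0.0609, 0.513 and 5.63 CPM) and AT1G14550 (levels 0.2, 0.118, 1.11 and 14.4 CPM) moved furthest toward AvrRpt2. BGLU22 (AT1G66280, levels 0.205, 2.02, 161 and 61.4 CPM), AT1G29100 (levels 0.0148, 0.0726, 8.77 and 2.19 CPM) and MSL9 (AT5G19520, levels 0.0888, 0.564, 12.4 and 4.94 CPM) moved furthest toward AvrRps4. In favour of AvrRpt2, 13 of 22 indolic defence genes rose and 0 fell (median 0.91, list alone 14 and 0, adjusted p = 4.43e-19). 10 of 24 PTI genes rose and 0 fell (median 0.49, list alone 12 and 0, adjusted p = 6.03e-12), and 8 of 19 ethylene genes rose and 0 fell (median 0.53, list alone 10 and 0, adjusted p = 8.59e-10). Weaker were shifts toward and away from AvrRpt2 in 5 and 1 of 16 chaperone genes (list alone 13 and 1), 5 and 1 of 14 GST genes (list alone 7 and 1) and 2 and 0 of 15 cell death genes (list alone 7 and 1). Adjusted p was 8.17e-06 to 0.0217, and adjusted p = 0.276, 0.453 and 0.331 with an estimated correlation. Mostly away from AvrRpt2 were 0 and 12 of 38 photosynthesis genes (list alone 0 and 32) and 0 and 3 of 21 clock genes (list alone 0 and 4). Adjusted p was 5.68e-13 to 0.00787, and adjusted p = 0.299 and 0.299 with an estimated correlation. PAD3 (1.43 ± 0.30) and RPS4 (0.42 ± 0.12) shifted toward AvrRpt2. Not passing were PR1 (1.49 ± 1.14), ICS1 (-0.67 ± 0.36), FMO1 (0.22 ± 1.18), FRK1 (0.56 ± 0.27), RRS1 (0.35 ± 0.17), RIN4 (-0.01 ± 0.10), EDS1 (-0.21 ± 0.18) and CCA1 (-0.09 ± 0.18) (adjusted p from 0.197 to 0.970). The test called 2164 genes, 1262 toward AvrRpt2 and 902 away (1057 and 1177 with scaling by total counts alone), or 1423 without AvrRpt2 replicate 3 at 20 h. Without 1 library the call changed (adjusted p) for ARD3 (0.0552 to 0.182, AvrRpt2 6 h 1, 2 and 3, AvrRps4 6 h 2 and 3, AvrRpt2 20 h 2 and 3 and AvrRps4 20 h 1 and 2), BGLU22 (0.0532 to 0.666, AvrRpt2 6 h 1, AvrRps4 6 h 1, 2 and 3, AvrRpt2 20 h 2 and 3 and AvrRps4 20 h 1 and 2), AT1G29100 (0.0523 to 0.419, AvrRpt2 6 h 1 and 2, AvrRps4 6 h 2 and 3, AvrRpt2 20 h 2 and AvrRps4 20 h 1), RPS4 (0.0745 to 0.102, AvrRpt2 6 h 2, AvrRps4 6 h 1, AvrRpt2 20 h 3 and AvrRps4 20 h 3), the clock genes (0.0605, AvrRpt2 20 h 2), the GST genes (0.0529, AvrRpt2 6 h 3) and the cell death genes (0.0570 to 0.0931, AvrRpt2 6 h 1 and AvrRpt2 20 h 3). Over 1.5-fold moves were to 5.58 for CYP82C3 (from 4.94), -1.61 for BGLU22 (from -4.73) and -2.62 for AT1G29100 (from -4.19) without AvrRpt2 6 h 1, 5.66 for CYP82C3 (from 4.94) and 5.58 for ARD3 (from 4.54) without AvrRps4 20 h 3, 3.56 for AT1G14550 (from 4.4) and -4.97 for MSL9 (from -3.99) without AvrRps4 6 h 3 and -7.01 for AT1G29100 (from -4.19) without AvrRps4 6 h 1. Calls that ended with other settings (adjusted p) were those of BGLU22 (0.114) and RPS4 (0.0523) with only these groups fitted, RPS4 (0.0656) with total count scaling, ARD3 (0.0647) with no low-count filter and ARD3 (0.0731) and AT1G29100 (0.0640) with halved counts. Fry did not call the GST genes (0.104).

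Mock groups show what flooding, handling and time of harvest did together, because the untreated group has no stated time. At 6 h AT4G39610 (at least 722-fold), AT3G12910 (at least 432-fold) and AT3G54530 (1904-fold to 56805-fold by the interval) were furthest above untreated, and AT2G27420 (-8.37 ± 0.43), AT2G15020 (-6.51 ± 0.30) and AT5G66740 (-6.28 ± 0.39) furthest below. No list passed with an estimated correlation. Members higher and lower were 22 and 1 of 24 PTI genes, 15 and 3 of 23 WRKY genes, 18 and 1 of 22 indolic defence genes, 13 and 0 of 14 GST genes, 14 and 1 of 19 ethylene genes, 18 and 3 of 30 jasmonate genes and 12 and 1 of 16 NLR genes. Adjusted p was 1.23e-12 to 0.0136, and adjusted p = 0.0534, 0.0534, 0.0534, 0.0534, 0.102, 0.453 and 0.298 with an estimated correlation. Next came 12 and 2 of 15 cell death genes, 7 and 4 of 14 hypoxia genes and 12 and 9 of 21 clock genes. Adjusted p was 0.00536 to 0.0306, and adjusted p = 0.282, 0.378 and 0.298 with an estimated correlation. Mostly lower were 1 and 33 of 38 photosynthesis genes (list alone 1 and 34) and 0 and 21 of 21 cell cycle genes. Adjusted p was 1.14e-06 to 0.00115, and adjusted p = 0.415 and 0.415 with an estimated correlation. The level of CCA1 was 228 ± 14.1 CPM in untreated seedlings and 18.9 ± 2.05 CPM in mock. From the fixed set PR1 (-2.06 ± 0.91), PAD3 (7.34 ± 0.29), FRK1 (3.89 ± 0.22), RPS4 (2.03 ± 0.09), RRS1 (0.44 ± 0.12), RIN4 (1.53 ± 0.07) and CCA1 (-3.59 ± 0.14) differed and ICS1 (0.24 ± 0.27), FMO1 (1.79 ± 1.61) and EDS1 (0.21 ± 0.13) (adjusted p from 0.142 to 0.430) did not. Of 15843 genes called 7698 were higher in mock. With scaling by total counts alone 6820 were higher and 9005 lower, a median shift of -0.12 over all genes. Leaving out 1 library changed the call (adjusted p) of PR1 (0.0626 to 0.157, untreated 1, 2 and 3 and mock 1 and 3). Values that moved over 1.5-fold became 15.18 for AT3G54530 (from 12.50) without untreated 1, -10.22 for AT2G27420 without mock 3 and -4.25 for PR1 without mock 2. The call ended (adjusted p) for PR1 (0.107) with only these groups fitted, PR1 (0.0582) with no low-count filter and PR1 (0.0686) with halved counts.

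In mock at 12 h AT4G25930 (at least 1348-fold), AT1G71000 (at least 625-fold) and AT3G54530 (547-fold to 16319.8-fold by the interval) were furthest above untreated. LHCB2.3 (AT3G27690, -8.17 ± 0.26), LHCB2.2 (AT2G05070, -7.77 ± 0.20) and CIPK20 (AT5G45820, -7.54 ± 0.30) were furthest below. 0 of 38 photosynthesis genes were higher and 38 lower (median -2.03, adjusted p = 2.58e-61), with LHCB3 (AT5G54270, -5.16 ± 0.13) called. 14 of 14 GST genes were higher and 0 lower (median 2.6, adjusted p = 6.09e-16), with GSTU3 (AT2G29470, 7.02 ± 0.37) called. 3 of 25 auxin genes were higher and 16 lower (median -1.28, adjusted p = 0.00108), with IAA6 (AT1G52830, 21.0-fold to 646-fold lower by the interval) called. Weaker were 13 and 3 of 23 WRKY genes, 17 and 3 of 22 indolic defence genes and 0 and 21 of 21 cell cycle genes. Adjusted p was 4.22e-07 to 0.00571, and adjusted p = 0.105, 0.105 and 0.658 with an estimated correlation. CCA1 stood at 4.92 ± 0.762 CPM in mock. FMO1 (4.58 ± 1.16), PAD3 (5.72 ± 0.27), RPS4 (1.28 ± 0.09), RIN4 (0.44 ± 0.07) and CCA1 (-5.53 ± 0.15) differed, and PR1 (-1.18 ± 0.79), ICS1 (-0.38 ± 0.27), FRK1 (0.16 ± 0.22), RRS1 (0.13 ± 0.12) and EDS1 (-0.28 ± 0.13) (adjusted p from 0.0685 to 0.563) did not. Called genes numbered 12878, 6423 higher and 6455 lower in mock. With scaling by total counts alone 8839 were higher and 4412 lower, a median shift of 0.21. Calls that turned without 1 library (adjusted p) were those of FMO1 (0.2, mock 1), ICS1 (1.62e-05, mock 1) and EDS1 (6.92e-04, mock 1). Moved by over 1.5-fold, values were 13.39 for AT3G54530 (from 10.71) and 5.60 for FMO1 without untreated 1, -8.46 for IAA6 (from -5.98) without mock 2 and 1.38 for FMO1 without mock 1. Other settings ended calls (adjusted p): FMO1 (0.122) with only these groups fitted.

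Mock at 20 h was the closest to untreated, with 6102 genes called, 3478 of them higher in mock. AT1G52560 (7.76 ± 0.77), SUC7 (AT1G66570, 6.40 ± 0.59) and DIN2 (AT3G60140, 6.24 ± 0.74) were furthest above untreated and BAM5 (AT4G15210, -2.95 ± 0.56), PR2 (AT3G57260, -2.51 ± 0.55) and XTH17 (AT1G65310, -2.32 ± 0.30) furthest below. 12 of 14 GST genes were higher and 0 lower (median 1.19, list alone 13 and 0, adjusted p = 2.65e-26), with GSTU3 (5.48 ± 0.38) called. Weaker were 12 and 2 of 23 WRKY genes (list alone 14 and 3), 13 and 3 of 22 indolic defence genes (list alone 15 and 3), 9 and 2 of 30 jasmonate genes (list alone 9 and 3), 10 and 5 of 21 clock genes (list alone 11 and 6), 0 and 33 of 38 photosynthesis genes (list alone 0 and 35) and 0 and 14 of 21 cell cycle genes (list alone 0 and 16). Adjusted p was 1.52e-12 to 0.0341, and adjusted p = 0.167, 0.167, 0.649, 0.392, 0.392 and 0.392 with an estimated correlation. CCA1 was at 270.3 ± 15 CPM in mock. PAD3 (2.67 ± 0.25), FRK1 (-1.51 ± 0.25), RPS4 (0.26 ± 0.09) and RIN4 (0.20 ± 0.07) differed, and PR1 (-1.45 ± 0.83), ICS1 (0.03 ± 0.27), FMO1 (0.97 ± 1.77), RRS1 (-0.18 ± 0.12), EDS1 (0.02 ± 0.13) and CCA1 (0.24 ± 0.12) (adjusted p from 0.138 to 0.949) did not. Without 1 library the call changed (adjusted p) for RPS4 (0.0776 to 0.175, untreated 1 and mock 1 and 2), RIN4 (0.0550 to 0.0973, untreated 1 and 3 and mock 1, 2 and 3), the jasmonate genes (0.132 to 0.527, untreated 2 and mock 2) and the clock genes (0.0522 to 0.0667, untreated 1 and mock 3). Over 1.5-fold moves were to 11.87 for AT1G52560 without untreated 2, 7.35 for SUC7 without untreated 3, 7.21 for DIN2 without untreated 1 and 5.45 for DIN2 without mock 3. Calls that ended with other settings (adjusted p) were those of the clock genes (0.0511) with halved counts.

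From 6 to 12 h within mock AT3G28270 (4.88 ± 0.47), AT1G60590 (4.45 ± 0.21) and AT2G15020 (4.33 ± 0.30) rose most and IGMT3 (AT1G21110, -5.43 ± 0.17), AT5G59680 (-5.10 ± 0.24) and MSRB7 (-5.05 ± 0.37) fell most. 2 of 24 PTI genes rose and 20 fell (median -1.39, adjusted p = 3.37e-13). 2 of 22 indolic defence genes rose and 15 fell (median -1.5, adjusted p = 9.72e-11), and 1 of 19 ethylene genes rose and 15 fell (median -0.84, adjusted p = 3.14e-05). 5 of 21 clock genes rose and 13 fell (median -0.80, adjusted p = 3.10e-06). Rises and falls with weaker support were 2 and 33 of 38 photosynthesis genes, 3 and 19 of 30 jasmonate genes, 3 and 12 of 23 WRKY genes, 1 and 13 of 14 GST genes, 2 and 12 of 16 NLR genes, 2 and 7 of 15 cell death genes and 9 and 0 of 21 cell cycle genes (list alone 7 and 0). Adjusted p was 1.76e-25 to 0.0492, and adjusted p = 0.104, 0.390, 0.144, 0.399, 0.390, 0.383 and 0.707 with an estimated correlation. The cell death median was -0.15, and 0.18 with scaling by total counts alone. FMO1 (2.79 ± 0.93), PAD3 (-1.62 ± 0.22), FRK1 (-3.73 ± 0.22), RPS4 (-0.75 ± 0.09), RRS1 (-0.31 ± 0.12), RIN4 (-1.09 ± 0.07), EDS1 (-0.49 ± 0.13) and CCA1 (-1.94 ± 0.14) changed, and PR1 (0.88 ± 0.98) and ICS1 (-0.62 ± 0.27) (adjusted p from 0.0511 to 0.458) did not. The value of RRS1 was 0.02 with scaling by total counts alone. Of 13062 genes called 6732 rose and 6330 fell, or 10693 and 3641 with scaling by total counts alone, a median shift of 0.33. Leaving out 1 library changed the call (adjusted p) of FMO1 (0.0577 to 0.646, mock 6 h 3 and mock 12 h 1), RRS1 (0.0626 to 0.152, mock 6 h 1 and mock 12 h 1 and 3), ICS1 (9.07e-07, mock 12 h 1) and the cell cycle genes (0.0660 to 0.177, mock 6 h 1 and mock 12 h 2). Values that moved over 1.5-fold became 5.70 for AT3G28270 without mock 6 h 1 and -5.71 for MSRB7 and -0.41 for FMO1 without mock 12 h 1. The call ended (adjusted p) for FMO1 (0.242) with only these groups fitted, the cell cycle genes (0.160) and EDS1 (0.306) with total count scaling and the cell cycle genes (0.0501) with halved counts.

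From 12 to 20 h within mock, light-harvesting genes rose. LHCB2.2 (7.43 ± 0.20), LHCB2.3 (7.15 ± 0.25) and BBX16 (AT1G73870, 7.47 ± 0.32) rose most and JMJD5 (AT3G20810, -5.96 ± 0.19), FKF1 (AT1G68050, -5.86 ± 0.30) and AOX1B (AT3G22360, -5.39 ± 0.39) fell most. 38 of 38 photosynthesis genes rose and 0 fell (median 1.61, adjusted p = 3.24e-67), with LHCB3 (4.69 ± 0.13) changed. 15 of 25 auxin genes rose and 3 fell (median 1.04, list alone 16 and 3, adjusted p = 9.57e-04), with IAA6 (4.18-fold to 142-fold by the interval) changed. Weaker were rises and falls in 0 and 13 of 14 GST genes, 2 and 8 of 14 hypoxia genes, 1 and 10 of 23 WRKY genes, 3 and 14 of 22 indolic defence genes (list alone 3 and 15) and 8 and 2 of 16 chaperone genes. Adjusted p was 1.41e-06 to 0.0326, and adjusted p = 0.261, 0.337, 0.315, 0.315 and 0.584 with an estimated correlation. FMO1 (-3.61 ± 1.00), PAD3 (-3.05 ± 0.23), FRK1 (-1.67 ± 0.25), RPS4 (-1.02 ± 0.09), RRS1 (-0.31 ± 0.12), RIN4 (-0.23 ± 0.07) and CCA1 (5.78 ± 0.15) changed, and PR1 (-0.27 ± 0.89), ICS1 (0.42 ± 0.27) and EDS1 (0.30 ± 0.13) (adjusted p from 0.0550 to 0.833) did not. The test called 10815 genes, 5292 upward and 5523 downward, or 3573 and 7959 with scaling by total counts alone, a median shift of -0.18. Calls that turned without 1 library (adjusted p) were those of FMO1 (0.698, mock 12 h 1), RRS1 (0.0562 to 0.193, mock 12 h 1, 2 and 3 and mock 20 h 3), RIN4 (0.0556, mock 12 h 1), ICS1 (1.43e-05, mock 12 h 1), EDS1 (5.35e-04 to 0.0441, mock 12 h 1 and mock 20 h 3) and the chaperone genes (0.0571 to 0.0611, mock 12 h 2 and mock 20 h 2). Moved by over 1.5-fold, values were 6.25 for IAA6 (from 3.77) without mock 12 h 2 and -0.41 for FMO1 without mock 12 h 1. Other settings ended calls (adjusted p): FMO1 (0.162) with only these groups fitted and the chaperone genes (0.0695) with total count scaling.

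RPS2 (AT4G26090), the receptor for AvrRpt2, and MYC2 (AT1G32640), a regulator of jasmonate responses, had no count in any of the 30 libraries. In the reference annotation genes of the opposite strand cover the exons of RPS2 to 100% (2 genes) and those of MYC2 to 98.5% (1 gene). Of 439 protein-coding genes of the nucleus covered to at least 95%, 412 had no count (93.8%), against 2237 of 20867 without such cover (10.7%). Both genes are left out of the list counts, and nothing can be said here of their expression.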

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

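The 3 tests of a difference between 2 effects come first. In each of them, hours since inoculation and time of day run together. The tests of time of day, the wrong label and the regrouped libraries were chosen after the results were seen, and those of gene overlap, mixed libraries and the order of the responses before. For AvrRpt2, 20 h against 6 h, 13425 genes changed in effect. The list medians of that difference were 1.5 for PTI genes, 2.11 for WRKY genes, 2.56 for indolic defence genes, 2.34 for jasmonate genes, 1.36 for ethylene genes and 1.54 for cell death genes, and, in lists with adjusted p = 0.0805, 0.0595, 0.142, 0.0805, 0.0805, 0.482, 0.0805 and 0.266 with an estimated correlation, 2.75 for salicylic acid genes, 0.80 for NLR genes, 0.94 for abscisic acid genes, -1.51 for auxin genes, -1.48 for photosynthesis genes, -0.93 for cell cycle genes, 1.37 for chaperone genes and 1.58 for GST genes. Single genes had 4.95 for PR1, 3.36 for ICS1, 7.95 for FMO1, 2.69 for PAD3, 4.18 for FRK1, 1.36 for RPS4, 0.46 for RRS1, 1.21 for RIN4 and 2.06 for EDS1. Without replicate 2 of mock at 6 h PR1 had 2.77, and the calls of PR1 and RRS1 ended without 1 library.

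For AvrRps4 the number was 12321. List medians were 1.02 for PTI genes, 1.96 for WRKY genes, 1.66 for indolic defence genes, 2.00 for jasmonate genes and 1.12 for cell death genes, and, in lists with adjusted p = 0.0563, 0.0563, 0.0928, 0.0556, 0.0973, 0.140, 0.521, 0.151 and 0.370 with an estimated correlation, 3.35 for salicylic acid genes, 0.68 for NLR genes, 0.79 for ethylene genes, 1.22 for abscisic acid genes, -1.37 for auxin genes, -1.03 for photosynthesis genes, -0.66 for cell cycle genes, 0.98 for chaperone genes and 1.08 for GST genes. The values of single genes were 3.46 for PR1, 4.03 for ICS1, 7.73 for FMO1, 1.26 for PAD3, 3.62 for FRK1, 0.95 for RPS4, 1.22 for RIN4 and 2.27 for EDS1, and PR1 had 1.27 without that library, 1 of 5 that end its call.

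The difference between the strains changed for 2164 genes. Medians of the lists were 0.49 for PTI genes, 0.91 for indolic defence genes and 0.53 for ethylene genes, and, in lists with adjusted p = 0.299, 0.299, 0.276, 0.453 and 0.331 with an estimated correlation, -0.43 for photosynthesis genes, -0.20 for clock genes, 0.41 for chaperone genes, 0.30 for GST genes and 0.21 for cell death genes. PAD3 and RPS4 had 1.43 and 0.42. Without 1 library, named with the results, the calls of the clock, GST and cell death lists and of RPS4 ended.

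With labels swapped within each time, 100 draws included 7 with as many genes for AvrRpt2 (12808 in a fit of these groups, highest other 14944) and 7 for AvrRps4 (12532, highest other 14367), but the 6 others in each case all kept the real 20 h groups, and so the 20 h effect. These counts do not settle whether chance can be excluded. For the difference between the strains 4 of 100 did (1902, highest other 3271). The 3 others there kept them too, and in no test did a draw that broke up the 20 h groups give as many. In each of the 14 comparisons of 2 groups, 1 of 10 splits, the real one, gave as many genes, and 10 splits are too few for a share under 0.05. The real numbers with only the compared groups were 4029, 11261 and 16142 for AvrRpt2 at 6, 12 and 20 h, 4629, 10154 and 15493 for AvrRps4, and 220, 563 and 4890 between the strains. For mock they were 15980, 12961 and 6769 against untreated and 13109 and 10764 between times. The highest other split gave 5 genes between the strains at 6 h and 0 elsewhere, where up to 1653 genes had an unadjusted p under 0.05 (edgeR).

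RPS2 and MYC2 had no count in any library. A count that leaves out reads lying over 2 genes and does not use the strand may account for this. Of protein-coding genes covered to at least 95% by genes of the opposite strand 93.8% had no count, against 10.7% without such cover. The value fits this explanation, and whether both genes are also silent here was not tested.

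Photosynthesis genes were lower in mock at 12 h than in untreated seedlings. The GST list passed upward in every mock group, with 13, 14 and 12 of 14 genes higher at 6, 12 and 20 h, but at 6 h it had adjusted p = 0.0534 with an estimated correlation. The time of day of the harvest may be a cause of either. In mock at 20 h, whose CCA1 level is nearest to untreated, the photosynthesis median was -0.42 against -2.03 at 12 h, so time of day and treatment cannot be told apart. The lowest GST median of the 3 mock groups was 1.19. This restates the pattern, and with no hour for the untreated harvest, time of day and treatment cannot be told apart here either.

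In mock at 12 h 22 of 25 salicylic acid genes were higher in replicate 1 than in both others, 9 of them at least 2-fold. Reads of an inoculated library mixed into it could do this, and other induced genes would then need the same share of such reads. Their share was at most 0.0783 times that of the salicylic acid genes, which speaks against it. The same holds for a wrong label: 0 other groups lay nearer to this library than mock at 12 h, at a distance of 0.427 against 0.838 for the next. Salicylic acid may have been active in those seedlings before or after mock treatment, which was not tested here.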

How the results depend on the processing

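List tests were run with total count scaling, halved counts, the block and each library left out, which ended 5, 3, 0 and 16 calls, added 1, 0, 0 and 20 and changed no direction of a list that had passed. Fry, which tests members against no change and not against other genes, passed 61 lists that camera did not and missed 5 that it did, and 2 medians of the cell death list changed sign with total count scaling. With DESeq2, RLE scaling, total count scaling, no low-count filter, halved counts and the block, the counts of genes stayed within 1.5-fold, except that DESeq2 called 750 and 1577 genes between the strains at 6 and 12 h. A fit of only the compared groups called 220 and 563 there, and the cause was not tested. Replicates of 2 groups share only a number: same-number correlations ran from -0.0981 to 0.147, in 5 of 45 pairs of groups every library correlated best with its own number, and replicate number as a block moved no count by over 1.5-fold. By construction a 2-fold minimum lowered every count, to 786, 3244 and 8740 for AvrRpt2 at 6, 12 and 20 h, 579, 2913 and 6990 for AvrRps4, 31, 100 and 639 between the strains, 8039, 4664 and 1153 for mock against untreated, 4388 and 2878 between mock times, 6660, 5289 and 338 for the interactions and 424, 2383 and 6440 for genes shared by the strains.

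Without 1 library the counts ran from 38 to 527 between the strains at 6 h, 253 to 1376 at 12 h, 3257 to 4970 at 20 h and 1423 to 2349 for their difference over time, and the other counts kept within 1.5-fold. Of 173 list calls 57 held with an estimated correlation. Examples from lists were chosen for steadiness after the fact: of all 1358 values the naming rule allows, 274 changed call or sign in at least 1 refit. Of 362 values of named genes 34 lost and 10 gained the call without 1 library. Calls lost and gained were 1 and 3 with DESeq2, 2 and 1 with RLE scaling, 3 and 3 with total count scaling, 6 and 0 with no low-count filter, 14 and 18 with only the compared groups, 5 and 1 with halved counts and 2 and 0 with the replicate block, the 2 lost being HRA1 between the strains at 6 h and AT4G36430 at 12 h. Among genes named whatever their values, 21 values changed sign under a setting, 2 of them called, and the cause was not tested. The lowest and highest values without 1 library follow. In AvrRpt2 at 6 h they were -0.29 to 0.00963 for CCA1, -0.0444 to 2.86 for PR1 and -0.0166 to 0.25 for RRS1. The values in AvrRps4 at 6 h were -0.0889 to 2.97 for PR1 and -0.0122 to 0.10 for RIN4. In the strains at 6 h they were -0.17 to 0.0148 for EDS1, -0.28 to 0.35 for FMO1, -0.24 to 0.0158 for FRK1, -0.0115 to 0.15 for ICS1, -0.83 to 0.77 for PR1, -0.14 to 0.0632 for RPS4 and -0.14 to 0.12 for RRS1. The values in the strains at 12 h were -0.21 to 0.17 for FRK1. In mock at 20 h against untreated they were -0.0683 to 0.0841 for EDS1 and -0.0949 to 0.12 for ICS1. The values in mock at 12 against 6 h were -0.41 to 3.37 for FMO1. In mock at 20 against 12 h they were -1.26 to 0.17 for PR1. The values in the strain difference at 20 against 6 h were -0.22 to 0.0759 for CCA1, -0.20 to 0.44 for FMO1 and -0.0380 to 0.0323 for RIN4. With total count scaling RRS1 had -2.03e-04 and RIN4 -0.0334 at 6 h with AvrRpt2 and AvrRps4, and RRS1 0.0211 in mock at 12 against 6 h. RIN4 in the strain difference had 0.00329 with DESeq2 and 0.00320 with RLE scaling.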

Other observations

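Single members moved within lists that did not pass. With AvrRpt2 at 20 h PYK10 (AT3G09260, a root beta-glucosidase, 2.16 ± 0.14) rose while the other root markers did not pass, and SWEET12 (AT5G23660, a phloem sucrose exporter, 2.07 ± 0.14) rose among the vascular markers. In the clock list BOA (AT5G59570, a MYB factor of the clock, 3.87 ± 0.21) and PRR5 (AT5G24470, an evening repressor of the clock, 2.01 ± 0.17) rose and CHE (AT5G08330, a repressor of CCA1, -2.49 ± 0.12) and CDF1 (AT5G62430, -2.03 ± 0.19) fell.

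The next test was written before its result was seen. Genes that differ between the strains at 12 h may do so because the AvrRpt2 response runs ahead of the AvrRps4 response. Of 1031 such genes 68.7% differed in the direction of the AvrRps4 effect at 20 h, where all tested genes gave 58.0%. The share was 86.0% of genes higher and 44.0% of genes lower with AvrRpt2. Of 6 jasmonate genes 1 fitted. The value lies between the limits set for and against, so the test cannot decide.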
